A study of Mus musculus with 2 samples.

How the data were processed

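The data are single-cell 3′ RNA libraries of mouse spleen cells sorted as CD45.2+CD11b+, 1 library labelled low B12 and 1 labelled high B12, and both were used. The deposited matrices hold raw UMI counts per gene and barcode, without normalization, made by the authors with Cell Ranger 4 per the file headers. The submitters' processing notes name Cell Ranger 2.1.1 instead, but the headers of both matrix files themselves name version 4. The other deposited files list barcode sequences and gene IDs with symbols in matrix order. The matrices hold all barcodes, empty droplets included, 1256219 in the low-B12 and 1053362 in the high-B12 library. Per the labels the kit was a 10x Genomics 3′ v2 kit, yet the 16-base barcodes of the low-B12 library are more distinct sequences than the barcode list of that version holds, so the kit version is left open. The genome build and annotation behind the counts are not given in the sources used here. Of the 32285 gene IDs, 32235 (99.8%) occur in GENCODE M21, from which gene positions in GRCm38 were taken. No column of the files was left unused.

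Cells were barcodes with at least 500 UMIs, 200 genes and at most 10% of UMIs from the 13 mitochondrial genes, by the same limits in both libraries. In the low-B12 library 6823 barcodes reached the UMI limit and 6813 the gene limit, and 303 (4.45%) were then left out for mitochondrial UMIs. In the high-B12 library these numbers were 7287, 7272 and 524 (7.21%). Scrublet, run per library within scanpy, called 509 (7.82%) and 346 (5.13%) barcodes as doublets, which were left out. This gave 6001 low-B12 and 6402 high-B12 cells, which held 77.8% and 81.6% of all UMIs of their library. Median mitochondrial shares were 2.15% and 1.34%. Median UMIs were 2701.5 and 3045 within neutrophil-like cells and 7514 and 8345 within monocyte-like cells, low-B12 library first.

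Counts were scaled to 10000 per cell and log-transformed, and 2000 variable genes were chosen within each library. Values were scaled and limited to 10, and 30 principal components and 15 neighbours fed Leiden clustering at resolution 1 with seed 1, without correction between libraries. The 19 clusters were named from markers of 16 classes. A marker counted when it had at least 100 CPM and at least 2 times the CPM of all other cells after adding 10 CPM to each, and the name was that of the class with the largest share of its markers, at least 3. A cluster stayed unnamed, as 4 did, when another class had at least 1 marker, and as many or more than the class itself, among its 10 leading genes at 200 CPM or more. Clusters without a marker of any class among those genes, such as 1 and 7, kept their name. The markers were fixed before the data were examined, while this scoring and tie rule were set afterwards. Classes are written as like a type, since names rest on RNA alone. Shares carry exact binomial intervals, and their differences describe these libraries only.

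For each class with at least 50 cells in each library, and over all cells, UMIs were summed and scaled to CPM by the class total. That made 9 groups beside all cells, of which 5 classes and 1 unnamed cluster are described. Genes needed at least 50 UMIs in both libraries together. The ratio of CPM, high-B12 over low-B12, has an exact conditional binomial interval, with 0.5 UMI added to each sum for log ratios. The size rule named up to 10 genes each way per class among genes at 200 CPM or more in a library whose interval excludes a ratio of 1.25 in either direction. It left out mitochondrial, ribosomal protein, haemoglobin, immunoglobulin segment and predicted genes and Xist. It also named up to 4 members at 50 CPM or more of each list discussed, and always the Tet genes, Mtr, Cd320, S100a8, S100a9, Il1b and Itgam where measured. Genes among the 10 leading genes of a cluster were then left out of the description of its class, apart from Il1b, because clustering on a gene and comparing it afterwards is circular. Naming markers outside those 10 are still described, namely Retnlg, S100a8 and S100a9 in neutrophil-like cells, Ly6c2, Ms4a4c and Itgal in monocyte-like cells and Fcmr in cluster 5, and for these the same circularity holds in part. The cluster 5 genes Jchain and Sox5 and the monocyte genes Cd36 and Lyz2 were left out for that reason. Some genes picked by the rule are not reported here.

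Of 24 gene lists fixed before the data were examined, those described were chosen after their values were seen. They cover type I interferon, interferon gamma, oxidative phosphorylation, inflammation, MHC class I and II, primary and secondary granules, S phase and G2 and M phase, immediate early genes, Tet and chromatin genes, and B12 metabolism. Each list with at least 5 measured genes has its median log2 ratio, an interval from 500 Poisson draws of the counts, and its percentile among 10000 random lists of the same size matched in 20 bins of mean expression. The percentile describes these libraries and is not a test. Free RNA was estimated from the median UMIs of barcodes ranked 10001 to 50000, which was 21 in the low-B12 and 31 in the high-B12 library, times the profile of barcodes with 1 to 100 UMIs. This rank range was set after the data were examined.

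Alternatives fixed beforehand changed the UMI minimum, the mitochondrial limit, doublet removal, the resolution, centring, depth, scaling, free RNA, cell weighting, the added UMIs and the gene minimum, and added a test against empty droplets. That test was a Monte Carlo multinomial test with 10000 draws at a false discovery rate of 0.001. Alternatives chosen after seeing the data were names forced on the unnamed clusters, shares among cells that are not neutrophil-like, clusters of a class weighted alike, and random lists matched on gene span as well, which was run for the interferon, oxidative phosphorylation and Tet lists.

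The ratio intervals, the size rule, the list percentiles and the empty droplet test were run on simulated data with known answers. Gene counts were drawn as independent Poisson counts, which is the error that the intervals assume. Counts held by few cells, clustering, class names and doublet calls were therefore not checked. The intervals held the true ratio for 95.7% of 8738 genes in a simulated neutrophil class and 95.7% of 10255 genes in a simulated monocyte class. All 16 and 27 genes planted with a 2-fold ratio at 200 CPM or more had an interval that excludes 1.25, and 0 of 647 and 0 of 774 unchanged genes did. The limit of 10 genes each way was not part of this check. Of lists without a planted ratio 6% and 3% lay outside the central 95%. The empty droplet test gave p under 0.05 for 1% of 300 simulated empty droplets of 700 UMIs. Analyses ran in Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9, numba 0.67.0 and matplotlib 3.10.9. T cell-like cells were compared but are not described, since 70 and 50 cells are few for gene ratios, and raw reads were not used here.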

Results

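Single-cell 3′ RNA sequencing was carried out on mouse spleen cells sorted as CD45.2+CD11b+, with 1 library from a low-B12 and 1 from a high-B12 condition. CD45.2 is an allelic form of the pan-leukocyte antigen CD45, and CD11b, the integrin subunit encoded by Itgam, is carried by neutrophils and monocytes and by parts of the dendritic cell, NK cell and B cell compartments. Vitamin B12 is the cofactor of methionine synthase (Mtr) and of methylmalonyl-CoA mutase (Mmut). The series title sets the comparison in the context of Tet2-deficient blood formation, while the labels give neither a genotype nor a dose nor the number of mice behind a library. The low-B12 library held 48884220 UMIs and gave 6001 cells with a median of 5392 UMIs and 2083 genes per cell. The high-B12 library held 46994991 UMIs and gave 6402 cells with a median of 4071 UMIs and 1578.5 genes. Since each condition has 1 library there was no test between conditions. All intervals are at 95% and cover counting error only, and a difference between these libraries cannot be told apart from an effect of B12.

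The first comparison asked which cell classes the sorted cells fell into in each library. Neutrophil-like cells made up 48.2% of CD45.2+CD11b+ cells in the high-B12 library (exact binomial interval 47.0 to 49.5%, 3087 of 6402 cells) and 17.8% in the low-B12 library (16.8 to 18.8%, 1068 of 6001 cells), a 2.71-fold higher share. B cell-like cells made up 5.22% of the high-B12 library (334 cells) and 22.2% of the low-B12 library (1331 cells), a share 4.25-fold higher in the low-B12 library. With the unnamed cluster 5, which holds 11 of 12 B cell markers, counted in, these shares were 9.81% and 27.3%, a 2.78-fold ratio. Monocyte-like cells made up 16.6% and 26.0% in the high-B12 and low-B12 library, and NK/ILC-like cells 13.2% and 15.3%. Neutrophil progenitor-like cells, led by the granule protease genes Elane and Mpo and by histone genes, made up 1.11% of the high-B12 library (71 cells) and 0.433% of the low-B12 library (26 cells). This difference of 0.676 points was 2.21 points with doublets kept and 1.40 points at resolution 2.

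Conventional dendritic cell-like (cDC-like) cells made up 3.97% of the high-B12 and 4.07% of the low-B12 library, T cell-like cells 0.781% and 1.17% (a share 1.49-fold higher in the low-B12 library), and macrophage-like cells 0.531% and 0.400%. The cDC-like class was cluster 13 alone, with 3 of 16 cDC markers, while the unnamed cluster 18 had 8 of them. With the unnamed clusters 17 and 18 counted in, cDC-like shares were 9.09% in the high-B12 and 11.2% in the low-B12 library. The macrophage-like difference of 0.131 points was −0.437 points with a minimum of 300 UMIs and −0.164 points in cells thinned to 500 UMIs. Clusters 5, 16, 17 and 18 were left unnamed because genes of another class stood among their leading genes, under a tie rule set after the data were seen. They made up 4.59%, 0.687%, 1.67% and 3.45% of the high-B12 library and 5.13%, 0.350%, 1.77% and 5.38% of the low-B12 library. Among B cell-like cells, cluster 9 held 71.4% in the low-B12 library (950 cells) and 32.3% in the high-B12 library (108 cells), where cluster 4 held 67.7%. A cluster mostly of 1 library may be that library and not a type. Among monocyte-like cells, cluster 11, led by Cd36, Pparg, Fabp4, Ace and Eno3, held 31.8% in the low-B12 and 14.2% in the high-B12 library.

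Because shares sum to a fixed total, they were also taken over the cells that were not neutrophil-like, 4933 in the low-B12 and 3315 in the high-B12 library. On that basis monocyte-like cells were at 31.6% in the low-B12 library and 0.433 percentage points higher in the high-B12 library. NK/ILC-like cells were at 18.7% and 25.5%, cDC-like cells at 4.95% and 7.66%, B cell-like cells at 27.0% and 10.1%, and T cell-like cells at 1.42% and 1.51%, low-B12 library first. These shares again sum to a fixed total. The lower B cell-like share therefore raises those of the other classes in the high-B12 library. Over all cells again, the difference for B cell-like cells was −17.0 percentage points (high minus low, interval −18.2 to −15.8). It was −4.98 points when log values were centred within each library before clustering, a setting that left 15.2% of low-B12 and 6.83% of high-B12 cells in unnamed clusters. Also over all cells, the cDC-like difference of −0.0985 points (−0.804 to 0.604) lay between −1.51 and −6.30 points under the alternatives that drew the clusters anew, which gave the class to other clusters.

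**Figure D1:**
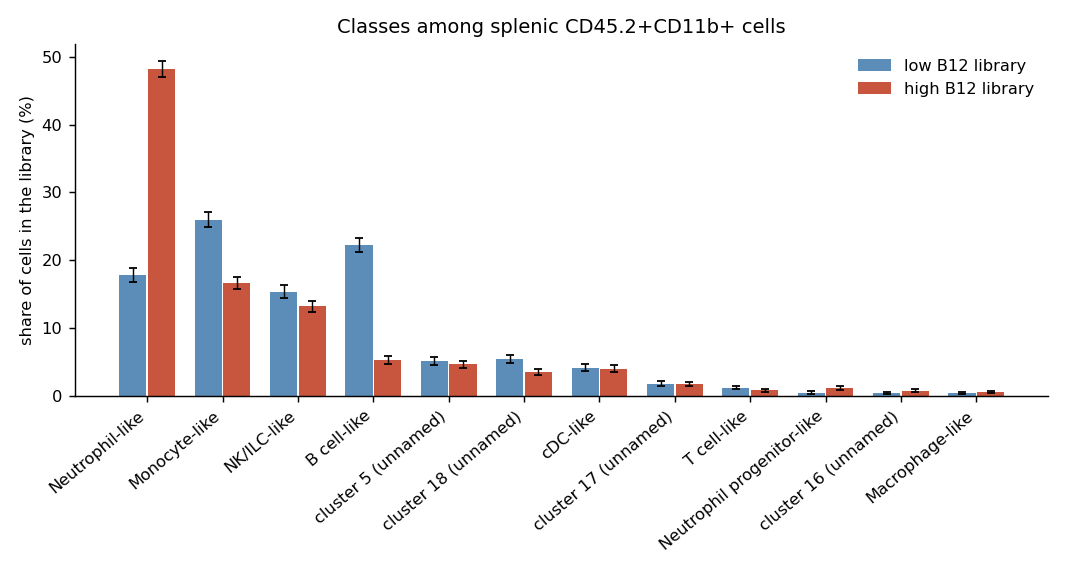
Share of CD45.2+CD11b+ cells in each class (y axis, percent of the cells of a library) for the low-B12 (blue) and high-B12 (red) library, with exact 95% binomial intervals of counting error as error bars. Neutrophil-like cells stand at 17.8% and 48.2% and B cell-like cells at 22.2% and 5.22%, low-B12 library first.

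In neutrophil-like cells (median 2701.5 UMIs per cell in the low-B12 and 3045 in the high-B12 library, 8740 genes measured), type I interferon genes were higher as a group in the high-B12 library. Ifi27l2a, an interferon-induced gene (ENSMUSG00000079017, chromosome 12, 103442167 to 103443680 in GRCm38), stood at 237 CPM (counts scaled to a common total) in the low-B12 and 529 CPM in the high-B12 library, a ratio of 2.23 (2.09 to 2.38). Pairs of CPM are given with the low-B12 library first from here on. Of 32 measured genes of the type I interferon list, 28 were higher in the high-B12 library, 11 of them by 1.5-fold or more, for example Irf7 (31.5 and 52.6 CPM) and Rtp4 (36.8 and 57.2 CPM). The list's median log2 ratio was 0.31 (0.26 to 0.44), at percentile 100 among 10000 random lists matched on mean expression. Within clusters 6, 8 and 14 it was 0.42, 0.33 and 0.17, and within cluster 7, which interferon genes lead, it was 0.06 (−0.07 to 0.21, 17 of 29 higher). Retnlg, a resistin-like gene of granulocytes (ENSMUSG00000022651, chromosome 16, 48872621 to 48874496), was 1.45-fold higher in the high-B12 library (5760 and 8369 CPM, 1.43 to 1.47), and is among the markers that name clusters 6, 7 and 14 of this class.

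Nabp1 (1.41-fold), the histone H3.3 gene H3f3b (1.40-fold) and AY036118 (1.31-fold) were the other genes named as higher. Genes named as lower in the high-B12 library were led by Tsc22d3, which encodes the glucocorticoid-induced leucine zipper (ENSMUSG00000031431, chromosome X, 140539528 to 140600659), at 391 and 225 CPM, 1.74-fold (1.64 to 1.84). They also held the chaperone genes Hsp90aa1 (317 and 210 CPM) and Hspa8 (406 and 282 CPM), the cyclin D3 gene Ccnd3 (628 and 432 CPM), the integrin gene Itga4 (307 and 215 CPM), Lrmda, Pip4k2a, Zfp36l2, Dgkh and Dennd4a, at 1.42-fold to 1.51-fold. The heat shock genes Hspa1b and Hspa1a were at 146 and 109 CPM in the low-B12 library against 31.7 and 39.4 CPM, and in cells thinned to 500 UMIs the Hspa1b log2 ratio was −0.37 in place of −2.20. The immediate early and dissociation stress list, which holds these chaperones, had 16 of 23 genes lower and a median log2 ratio of −0.24 (−0.34 to −0.20), which was −0.14 with clusters weighted alike. S100a8 and S100a9, the calprotectin genes, were 1.15-fold and 1.16-fold higher in the high-B12 library, at 111479 and 128310 CPM and at 110469 and 128177 CPM, and also name clusters of this class. The median log2 ratio over all measured genes was −0.15 in neutrophil-like cells and −0.10 in NK/ILC-like cells, and scaling by the median ratio of genes in place of the total adds 0.14 and 0.11 to every log2 ratio of these classes. With that scaling 8 of the 44 genes followed in neutrophil-like cells had a log2 ratio more than 1.5 times smaller or larger or of the other sign. So did 11 of 44 with every cell's CPM weighted the same, 12 of 41 in cells thinned to 500 UMIs and 0 of 44 with clusters weighted alike.

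Genes of inflammation and of neutrophil granules did not shift together in neutrophil-like cells. Of 30 inflammatory cytokine and NF-kB target genes, 15 were higher and 15 lower, with a median of −0.02 (0.12 when scaled by the median ratio of genes). Il1b, the interleukin-1β gene, was at 2894 and 2299 CPM, 1.26-fold lower in the high-B12 library (1.23 to 1.28). Cd14 was at 53.7 and 88.0 CPM, the NF-kB inhibitor gene Tnfaip3 at 83.9 and 54.1 CPM, the chemokine gene Cxcl2 at 898 and 1102 CPM and the chemokine receptor gene Cxcr4 at 356 and 262 CPM. Il1b is among the genes that define neutrophil clusters 6 and 8 and is given because it was fixed for reporting in every class. Of 17 secondary granule genes 10 were higher, with a median of 0.01 (−0.09 with clusters weighted alike), Hp at 1181 and 1393 CPM and Olfm4 at 19.5 and 107 CPM. Of 12 primary granule genes 9 were lower, with a median of −0.31 (−0.45 to −0.19). This rested on few cells, as 1 cell held 78.4% of the Mpo, 48.1% of the Elane and 50.4% of the Prtn3 UMIs of the class in the low-B12 library, and with doublets kept the median was 0.28 in a class that held other clusters.

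All 9 measured MHC class II genes were lower in neutrophil-like cells of the high-B12 library, with a median log2 ratio of −1.40 (−1.61 to −0.81). Cd74, the invariant chain gene, was at 155 and 48.8 CPM, H2-Eb1 at 54.6 and 15.9 CPM, H2-Aa at 52.6 and 17.4 CPM and H2-Ab1 at 64.6 and 22.4 CPM. The 10 cells with most Cd74 UMIs held 67.9% of them in the low-B12 library, out of 1068 cells, and 22.9% in the high-B12 library, out of 3087 cells. For Igkc the shares of the 10 leading cells went the other way, at 44.6% and 68.3%. B cell genes were lower beside the MHC class II genes, with Cd79a at 13.3 and 3.14 CPM and Ebf1 at 12.2 and 1.96 CPM. The more abundant Ighm (104 and 72.2 CPM), Igkc (76.1 and 39.9 CPM) and Bank1 (54.6 and 37.3 CPM) were lower by less. Of 27 S phase genes 25 were lower, with a median of −0.66 (−0.76 to −0.45) and Pcna at 116 and 84.3 CPM, while 13 of 24 G2 and M phase genes were lower, with a median of −0.10 (0.03 when scaled by the median ratio of genes). With doublets kept the MHC class II median was −0.32 and the S phase median −0.12, in a class drawn anew from which a cluster of 86 and 238 cells led by Fcnb and Elane went to the neutrophil progenitor-like class. Both medians were also much smaller in size in the same cells with every cell's CPM weighted the same, as given in the part on processing. Interferon genes such as Rsad2 and Ifit3 lead neutrophil cluster 7, whose size is therefore not compared, and the rule also picked Ifitm1 and, from the interferon list, Isg15, which define clusters of this class and are left out.

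In monocyte-like cells (1559 cells in the low-B12 and 1062 in the high-B12 library, 10265 genes measured), type I interferon genes were higher as a group in the high-B12 library. Chil3, which encodes the chitinase-like protein Ym1 (ENSMUSG00000040809, chromosome 3, 106147554 to 106167564), was at 416 and 801 CPM, 1.93-fold higher. Ifi27l2a stood at 1549 and 2483 CPM (1.60-fold), Bst2, the tetherin gene (ENSMUSG00000046718, chromosome 8, 71534255 to 71537456), at 124 and 215 CPM (1.73-fold), Ifi203 at 141 and 224 CPM, and Ly6c2, which encodes the monocyte antigen Ly6C2, at 462 and 702 CPM (1.52-fold). Of 35 measured type I interferon genes 33 were higher, 14 by 1.5-fold or more, with Rtp4 at 35.6 and 61.5 CPM and Oas1a at 31.5 and 54.2 CPM. The list's median log2 ratio was 0.52 (0.45 to 0.59, percentile 100), against −0.04 for 24 interferon gamma response genes, of which 10 were higher (0.05 when scaled by the median ratio of genes). The interferon median was 0.28 when every cell was thinned to 500 UMIs.

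Ms4a4c (1.56-fold), the haptoglobin gene Hp (1.48-fold) and Ms4a6b (1.43-fold) completed the genes named as higher, beside S100a8 and S100a9. Ly6c2 and Ms4a4c are among the markers that name cluster 3 and Itgal among those of cluster 11, so their values follow the mix of clusters in part. Secondary granule genes had a median of 0.34 with 10 of 14 higher, which was 0.16 with 8 higher when clusters were weighted alike. The same list was also higher in NK/ILC-like cells (0.62, 7 of 7) and B cell-like cells (0.64, 8 of 9), and its members Camp and Ngp were 2.41-fold and 2.71-fold higher in empty droplets of the high-B12 library. Primary granule genes had a median of 0.40 with 5 of 7 higher, such as the cathepsin C gene Ctsc at 298 and 392 CPM. Inflammatory cytokine and NF-kB target genes had a median of −0.03 with 13 of 30 higher (0.06 when scaled by the median ratio of genes), among them the chemokine genes Ccl3 at 97.6 and 146 CPM and Ccl4 at 47.2 and 82.5 CPM. MHC class II genes had a median of −0.03 with 7 of 14 higher (0.05 when scaled so). Lower in the high-B12 library were Tsc22d3 at 255 and 137 CPM (1.86-fold), Ccnd3 at 392 and 213 CPM (1.84-fold), Pag1 (1.83-fold), the ubiquitin ligase gene Cblb (1.77-fold), the phosphatase gene Dusp2 (1.75-fold), Sgms1, Sptan1, Stk10, Zmiz1 and Itgal, which encodes CD11a, at 484 and 300 CPM (1.61-fold). In monocyte-like cells the Fc receptor gene Fcgr4 was at 90.2 and 39.1 CPM, Pglyrp1 at 177 and 110 CPM, the cholesterol exporter gene Abcg1 at 81.0 and 47.4 CPM, the lipid transfer gene Pltp at 101 and 64.3 CPM and Cxcr4 at 118 and 66.1 CPM. The fatty acid binding gene Fabp5 was at 56.1 and 89.7 CPM. The survival genes Bcl2, Bcl2a1b and Bcl2a1d were at 112 and 64.8, 80.5 and 44.2, and 67.3 and 34.9 CPM. With clusters 2, 3 and 11 weighted alike in both libraries, a setting added after the data were seen, 18 of the 45 genes followed in this class had a log2 ratio more than 1.5 times smaller or larger or of the other sign. Examples are Fcgr4 at −0.44 in place of −1.20, Ly6c2 at 0.38 in place of 0.60 and Bcl2 at 0.01 in place of −0.78, while Chil3 stood at 0.75 in place of 0.95.

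**Figure D2:**
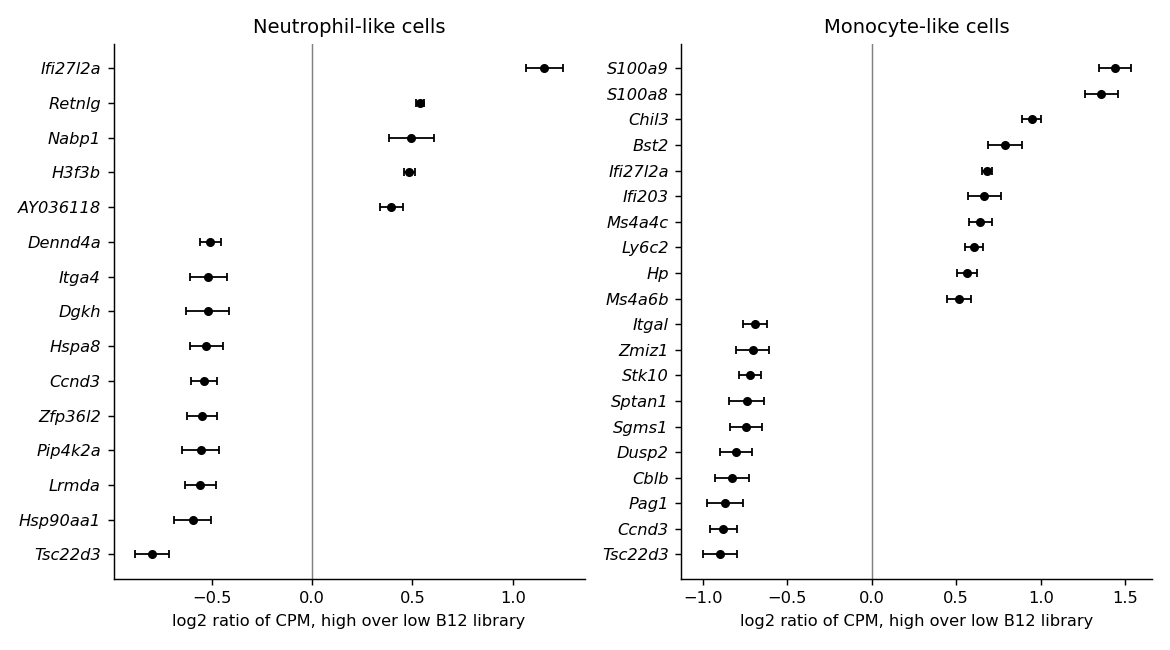
Log2 ratio of CPM (x axis, high-B12 over low-B12 library) of the genes picked by the size rule in neutrophil-like (left) and monocyte-like cells (right), leaving out the 10 leading genes of each cluster, with 95% intervals of counting error as bars. Ifi27l2a lies at ratios of 2.23 and 1.60 and Tsc22d3 is 1.74-fold and 1.86-fold lower in the high-B12 library.

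In NK/ILC-like cells (921 and 844 cells, 8896 genes measured), the chaperone genes Hspa1b and Hspa1a were lower and Ccl4 and Ccl3 higher in the high-B12 library. Hspa1b and Hspa1a, which encode inducible HSP70 chaperones, stood at 1275 and 741 CPM (1.72-fold, 1.64 to 1.80) and at 696 and 421 CPM (1.65-fold), and Hsph1 at 228 and 154 CPM. Ccl4 was at 1320 and 1915 CPM, 1.45-fold higher, and Ccl3 at 618 and 760 CPM. The inhibitory receptor gene Klra1 was at 167 and 252 CPM (1.51-fold, 1.36 to 1.67), Rgs1 at 171 and 240 CPM and AY036118 at 917 and 1273 CPM. Other genes named as lower were Trps1, Znrf3, Tbc1d5, Fhit, Aak1, Lnpep and the transcription factor gene Ets1 (588 and 402 CPM), at 1.46-fold to 1.57-fold. Genes with the longest spans were lower in general in this class, with a median log2 ratio of −0.30 against 0.14 for the shortest. The longest genes stood below the shortest in the other described classes too. No single named gene was set against genes of like span. The rule also picked Xcl1, which defines NK/ILC cluster 1 and is left out.

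MHC class I presentation genes were higher as a group in NK/ILC-like cells, with 17 of 21 higher and a median log2 ratio of 0.18, among them the immunoproteasome gene Psmb8 at 365 and 469 CPM. This list was not set against lists matched on gene span. H2-D1 stood at 2570 and 2987 CPM. Of 7 measured MHC class II genes 5 were higher (median 0.39, 0.14 to 0.56), and this median was −0.50 with doublets kept, when the class also held a cluster led by both NK and neutrophil genes such as Il2rb and Ltf. Of 22 type I interferon genes 13 were higher, with a median of 0.05 (−0.10 to 0.13). The immediate early and dissociation stress list, which includes Hspa1a, Hspa1b and Atf3 (139 and 84.6 CPM), had 16 of 25 genes lower and a median of −0.11, which was 0.01 when every cell's CPM was weighted the same.

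In B cell-like cells (1331 and 334 cells, 9360 genes measured, cluster 9 the larger in the low-B12 and cluster 4 in the high-B12 library), Tbx21, which encodes the transcription factor T-bet, was lower in the high-B12 library. Tbx21 (ENSMUSG00000001444, chromosome 11, 97098071 to 97115331) was at 281 and 154 CPM, 1.82-fold lower (1.62 to 2.07). The phosphatase genes Ptprj (405 and 215 CPM) and Ptpn22 (289 and 175 CPM), the immediate early gene Egr1 (250 and 149 CPM), Zbtb20 (1161 and 740 CPM), Phactr2, Grk5 and Ppp1r16b were lower by 1.55-fold to 1.88-fold. Ifi27l2a (207 and 338 CPM, 1.63-fold), Ifi203 (190 and 278 CPM), Shisa5 (276 and 450 CPM), Rgs1 (181 and 275 CPM), Ptp4a3, the histone H3.3 gene H3f3a and Gmfg were higher by 1.40-fold to 1.63-fold. The type I interferon list had 12 of 20 genes higher and a median of 0.16 (−0.03 to 0.28, percentile 99.3), an interval that includes 0. With clusters 4 and 9 weighted alike the median was −0.01, with 10 higher and 10 lower.

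Interferon gamma response genes were lower as a group in B cell-like cells of the high-B12 library, with 20 of 22 lower and a median log2 ratio of −0.26 (−0.43 to −0.17), among them the antigen processing genes Tap1 (111 and 85.8 CPM) and Tapbp (105 and 85.8 CPM) and the transcription factor gene Irf8 (472 and 401 CPM). Of 16 inflammatory cytokine and NF-kB target genes 11 were lower (median −0.19), such as Icam1 at 71.2 and 38.9 CPM, Gadd45b at 191 and 149 CPM and Relb at 62.4 and 49.5 CPM, and with doublets kept this median was 0.08. Pdzd2 and Nr3c2 were also picked but are among the genes that define clusters 4 and 9. With the clusters weighted alike 12 of 29 genes had a log2 ratio more than 1.5 times smaller or larger or of the other sign, such as Shisa5 at 0.16 in place of 0.70, and Rgs1 and Ptprj were of the other sign under other filters on mitochondrial UMIs (Rgs1 −0.09, Ptprj 0.01).

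In cDC-like cells (cluster 13, 244 and 254 cells, 7337 genes measured), Ifi27l2a was higher in the high-B12 library, at 875 and 1488 CPM (1.70-fold, 1.61 to 1.80). Spag9 (319 and 182 CPM), Tsc22d3 (271 and 158 CPM), Ust, Arhgap26, Ccnd3 (397 and 245 CPM), Lrmda, the hyaluronan receptor gene Cd44 (331 and 210 CPM), and Ubl3 were lower by 1.51-fold to 1.75-fold. Zbtb20 was at 334 and 223 CPM, and Ifi203 was 1.44-fold higher. Of 32 type I interferon genes 23 were higher (median 0.27, 0.12 to 0.34, percentile 100), with Irf7 at 64.7 and 89.5 CPM and Isg15 at 74.6 and 102 CPM. Immediate early and dissociation stress genes were lower, with 18 of 23 lower and a median of −0.23 (−0.26 to −0.17), among them Fosb (870 and 585 CPM), Klf2 (660 and 483 CPM) and Nr4a1 (127 and 82.5 CPM). MHC class II genes had a median of 0.15 (0.12 to 0.18) with 10 of 14 higher, such as H2-Oa at 126 and 170 CPM and H2-DMb2 at 38.6 and 50.2 CPM. This class depended on how clusters were drawn, and with log values centred within each library the interferon median was −0.20, the Ifi27l2a log2 ratio −0.84 and 17 of 27 genes were more than 1.5 times smaller or larger or of the other sign. Thinned to 500 UMIs, Isg15 was at −0.44 in place of 0.44 and Zbtb20 at 0.12 in place of −0.58.

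Across these classes, oxidative phosphorylation genes were higher in the high-B12 library by small amounts in each of 4 classes. In monocyte-like cells 56 of 57 genes were higher, with a median log2 ratio of 0.18 (0.16 to 0.19), for example Ndufa3 at 250 and 307 CPM, Cox7b at 252 and 305 CPM and Ndufc1 at 125 and 152 CPM. In NK/ILC-like cells 55 of 57 were higher (median 0.20, 0.17 to 0.22), such as Atp5j2 at 383 and 508 CPM, Sdhd at 47.8 and 64.3 CPM and Atp5e at 839 and 1035 CPM. In B cell-like cells 48 were higher (median 0.11), such as Atp5k at 168 and 214 CPM and Uqcr10 at 149 and 188 CPM, and in cDC-like cells 50 were higher (median 0.11). In neutrophil-like cells 22 of 57 were higher and the median was −0.02 (0.12 when scaled by the median ratio of genes). The monocyte median was 0.10 with every cell's CPM weighted the same and also 0.10 with the clusters weighted alike, the B cell median 0.06 with clusters weighted alike, and the cDC median was −0.13 with centred log values.

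**Figure D3:**
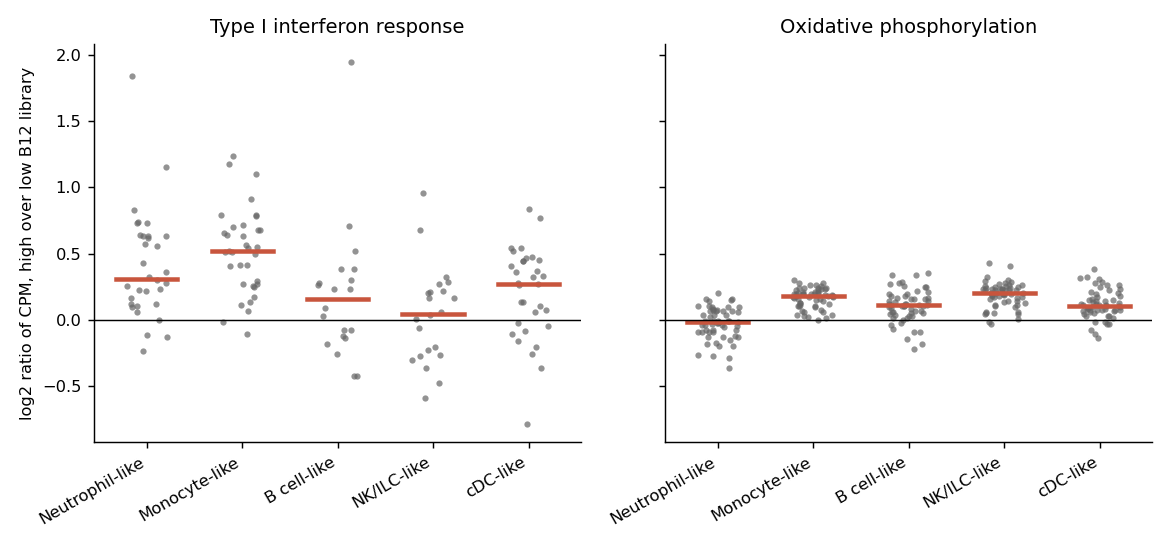
Log2 ratio of CPM (y axis, high-B12 over low-B12 library) of each measured gene (grey points) of the type I interferon (left) and oxidative phosphorylation (right) lists in 5 classes (x axis), with the median as a red line. Interferon medians were 0.31 in neutrophil-like and 0.52 in monocyte-like cells against 0.05 in NK/ILC-like cells, and oxidative phosphorylation medians were −0.02 in neutrophil-like cells (0.12 when scaled by the median ratio of genes) and 0.11 to 0.20 in the others (0.14 to 0.30 when scaled so).

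The Tet genes, Mtr and Cd320 were fixed for reporting in every class before the data were seen. Tet2, the DNA demethylase gene named in the series title (ENSMUSG00000040943, chromosome 3, 133463679 to 133545139), was at 94.3 and 75.9 CPM in neutrophil-like cells (ratio 0.804, 0.719 to 0.902) and at 158 and 139 CPM in monocyte-like cells (0.879, 0.815 to 0.947). The Tet2 ratio was 0.959 in NK/ILC-like, 0.922 in B cell-like and 0.910 in cDC-like cells, each with an interval that includes 1. In monocyte-like cells it was of the other sign with clusters weighted alike (log2 0.05). Counts of 3′ ends do not tell the Tet2 genotype, since a 3′ tag outside a deleted part would still be counted. Tet3 was lower in the high-B12 library in each of the 5 classes, with ratios of 0.689 in neutrophil-like, 0.756 in monocyte-like, 0.804 in NK/ILC-like, 0.711 in B cell-like and 0.737 in cDC-like cells. Genes with the longest spans were lower in general, with median log2 ratios of −0.23, −0.26, −0.30, −0.12 and −0.25 in the same order of classes. Neither Tet2 nor Tet3 alone was set against genes of like span. Tet1 had 52 and 61 UMIs over all cells.

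Of the Tet, Dnmt and chromatin regulator list, 12 of 15 genes were lower in neutrophil-like cells of the high-B12 library (median −0.35, −0.45 to −0.18), 12 of 15 in monocyte-like cells (−0.24), 14 of 14 in NK/ILC-like cells (−0.31, −0.42 to −0.23) and 14 of 15 in cDC-like cells (−0.30), against 7 of 15 in B cell-like cells (0.01). In NK/ILC-like cells the DNA methyltransferase genes Dnmt3a and Dnmt1 were at 52.2 and 33.7 CPM and at 59.1 and 39.4 CPM, Asxl1 at 73.5 and 53.5 CPM and the histone demethylase gene Kdm6b at 134 and 106 CPM. Kdm6a was at 62.6 and 47.3 CPM in neutrophil-like cells, Asxl1 at 93.4 and 67.5 CPM in monocyte-like cells, and Dnmt3a and Kdm6b at 66.4 and 46.0 CPM and 146 and 111 CPM in cDC-like cells. The median was 0.01 in monocyte-like cells thinned to 500 UMIs and −0.09 with their clusters weighted alike, −0.08 in B cell-like cells with clusters weighted alike, and 0.18 in cDC-like cells with centred log values. Long genes were lower in general in the high-B12 library, and among random lists matched on gene span as well as expression the list lay at percentile 0.650 in neutrophil-like, 11.7 in monocyte-like, 8.32 in NK/ILC-like and 3.16 in cDC-like cells.

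Genes of B12, folate and one-carbon metabolism had medians of −0.29 (−0.45 to −0.06) in neutrophil-like, −0.06 in monocyte-like (0.02 when scaled by the median ratio of genes), −0.17 in NK/ILC-like, 0.05 in B cell-like and −0.08 in cDC-like cells, with 16 of 19, 15 of 24, 16 of 22, 10 of 22 and 9 of 14 genes lower in the high-B12 library. With clusters 4 and 9 weighted alike the B cell median was −0.22, with 14 of 22 lower, and the NK/ILC median was 0.03 in cells thinned to 500 UMIs. Against random lists matched on mean expression the median in neutrophil-like cells lay at percentile 6.26. Mat2a, which encodes a subunit of S-adenosylmethionine synthase, was at 98.5 and 63.5 CPM in neutrophil-like cells (1.55-fold lower, 1.38 to 1.74) and at 217 and 203 CPM in monocyte-like cells. The transcobalamin gene Tcn2 was at 92.3 and 88.0 CPM in neutrophil-like cells, and Ggh at 108 and 118 CPM in monocyte-like cells. Mtr, the methionine synthase gene, rested on 29 and 34 UMIs in neutrophil-like cells (ratio 0.368, 0.218 to 0.628), and its ratios were 0.801 in monocyte-like, 0.657 in NK/ILC-like, 1.19 in B cell-like and 1.00 in cDC-like cells. Cd320, the transcobalamin receptor gene, had 120 and 67 UMIs over all cells, too few to split by class.

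The sort marker Itgam was at 615 and 566 CPM in neutrophil-like, 288 and 251 in monocyte-like, 265 and 222 in NK/ILC-like, 113 and 133 in B cell-like and 168 and 123 CPM in cDC-like cells. Its log2 ratio was 0.02 in neutrophil-like cells when scaled by the median ratio of genes, and negative in B cell-like cells under 5 alternatives, for example −0.33 at 5% mitochondrial UMIs. Il1b was at 62.0 and 60.3 CPM in monocyte-like and at 48.4 and 87.9 CPM in cDC-like cells.

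S100a8 and S100a9 were also higher in the high-B12 library in classes that are not neutrophils, where much of their level matched free RNA. In B cell-like cells S100a8 was at 55.3 and 246 CPM against 63.4 and 258 CPM that free RNA alone would give, and in NK/ILC-like cells at 71.5 and 319 CPM against 90.9 and 328 CPM. In monocyte-like cells it was at 120 and 308 CPM against 51.7 and 192 CPM, and in cDC-like cells at 32.2 and 265 CPM against 40.1 and 153 CPM. S100a9 (chromosome 3, 90692632 to 90695721, next to S100a8 at 90668978 to 90670035) stood at 119 and 322 CPM in monocyte-like, 64.6 and 272 CPM in B cell-like, 80.2 and 388 CPM in NK/ILC-like and 50.2 and 321 CPM in cDC-like cells, with 46.5 and 180, 57.1 and 243, 81.7 and 308, and 36.1 and 144 CPM as the level from free RNA.

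**Figure D4:**
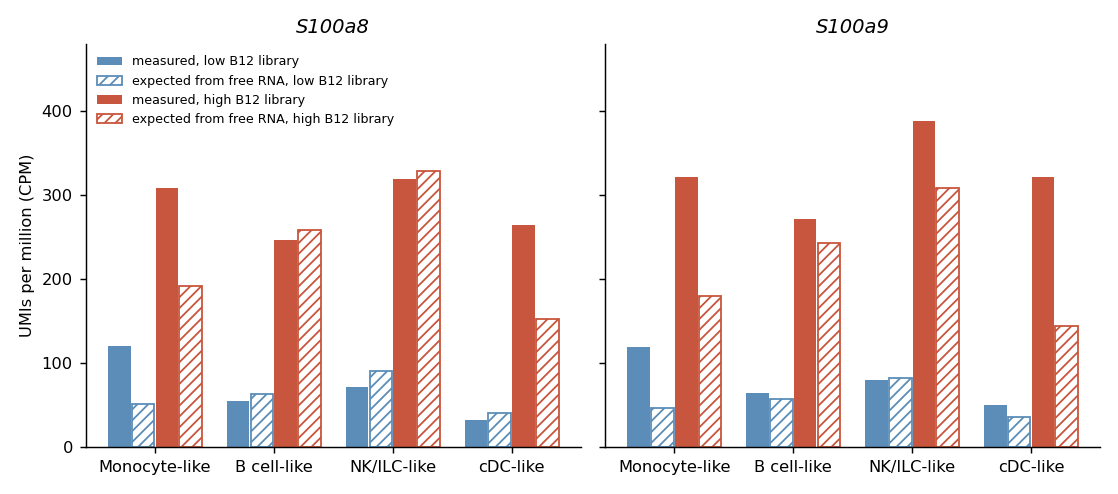
CPM (y axis) of S100a8 (left) and S100a9 (right) in 4 classes that are not neutrophils, as measured (filled bars) and as the level that free RNA alone would give (hatched bars), for the low-B12 (blue) and high-B12 (red) library. Both bars are higher in the high-B12 library in each class, with S100a8 in B cell-like cells at 246 CPM measured and 258 CPM from free RNA.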

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

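Of the tests in this part, the one of a whole-library shift and those that weight clusters alike or match on gene span were chosen after the result was seen. Differences between classes described here were not tested, since each condition has 1 library.

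Type I interferon genes were higher in monocyte-like cells of the high-B12 library, with a median log2 ratio of 0.52 (0.45 to 0.59). The median was 0.518 after the expected free RNA was removed, which argues against free RNA at the estimated amount only. That amount was 0.28% of the UMIs of this class in the low-B12 and 0.41% in the high-B12 library. Its removal could hardly have moved the median. A different mix of clusters may account for part, since the median was 0.418 with clusters weighted alike, only just within the limit of 0.8 times set for a pattern that stays, and the medians within clusters 2, 3 and 11 were 0.34, 0.35 and 0.17. A shift of the whole library is argued against by NK/ILC-like cells, whose median was 0.046 (−0.096 to 0.134) against a lower bound of 0.449 in monocyte-like cells. An effect of B12, another difference between the mice, or a batch difference that acts unevenly across classes stays open and untested.

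Oxidative phosphorylation genes were higher in 4 classes of the high-B12 library. Gene length is one technical reason, since in monocyte-like cells the genes with the longest spans had a median log2 ratio of −0.26 and those with the shortest 0.09. Against lists matched on expression and span the list stood above the central 95% in 3 of the 4 classes and at percentile 95.7 in B cell-like cells. This argues against length as the whole cause in those 3 classes, in the processing used first only, and the percentile is not a test. Matched lists reached 0.087 of the 0.179 seen in monocyte-like, 0.133 of 0.199 in NK/ILC-like, 0.069 of 0.108 in B cell-like and 0.070 of 0.105 in cDC-like cells. Span matching was not run with clusters weighted alike. The list medians were then 0.098 in monocyte-like, 0.064 in B cell-like and 0.201 in NK/ILC-like cells. The median in monocyte-like cells was 0.180 after removal of free RNA, which argues against that cause at the small amount estimated only. Length may account for much of it, and a hypothesis of a B12 effect stays untested.

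MHC class II genes had a median log2 ratio of 0.39 in NK/ILC-like and −1.40 in neutrophil-like cells, a gap of 1.79, picked out as a difference between groups of cells. With doublets kept, which also drew the clusters anew, these medians were −0.50 and −0.32, so the gap was not seen there. RNA of B cells in neutrophil droplets is a candidate explanation for the lower MHC class II values in neutrophil-like cells. There 11 B cell markers with at least 10 UMIs had a median of −2.08, while the MHC class II genes had at least 50 UMIs. The more abundant markers Ighm and Bank1 were lower by less. In the low-B12 library 10 cells held 90.0% of Cd79a UMIs. Free RNA is argued against, as the MHC class II median was −1.44 after its removal. Whether neutrophils themselves differ in these genes stays open.

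Primary granule genes had a median of 0.40 in monocyte-like and −0.31 in neutrophil-like cells, a gap of 0.706, also picked out as a difference between groups of cells. In the low-B12 library 1 neutrophil-like cell held 78.4% of the Mpo UMIs of its class. The monocyte and neutrophil medians were 0.39 and 0.28 with doublets kept and 0.23 and 0.12 with 300 UMIs per cell. In both settings the neutrophil-like class had changed, since a cluster led by genes such as Fcnb, Camp and Ngp was named progenitor-like in the one and unnamed in the other. No cause was tested for this gap.

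Empty droplets, which lie outside the cells compared, held more neutrophil RNA in the high-B12 library. S100a8 was at 18272 and 46839 CPM there, a ratio of 2.56, picked out as a signal in data outside the cells. S100a9 had a ratio of 2.68, Camp of 2.41 and Ngp of 2.71, while the MHC class II chain gene Cd74 and the immunoglobulin gene Igkc had ratios of 0.600 and 0.309. The neutrophil-like share of cells, 2.71-fold higher, and the B cell-like share, 4.25-fold lower (2.78-fold with cluster 5 counted in), lie in the same directions.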

How the results depend on the processing

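The settings that force names on unnamed clusters, take shares among cells that are not neutrophil-like, or weight clusters alike were chosen after the data were seen. Share differences are high-B12 minus low-B12 in percentage points and other values are log2 ratios. No paired analysis was possible because each condition has 1 library. For the values that differ here the cause was not tested. Gene ratios stayed inside the counting interval of their first value in 2355 comparisons with an alternative and left it in 527. In 24 they turned sign where that interval excluded 0. A gene with a wide interval could therefore shift far and still count as inside. Of the 2355, 192 with a gene minimum of 10 UMIs and 190 with 200 UMIs could not have differed. That minimum only picks which genes are kept. Another 192 came from adding 5 UMIs to each sum, which moves genes with many UMIs little. With 1000 UMIs per cell the cDC-like share was −1.52 and Itgam in B cell-like cells −0.23. With 300 UMIs the shares were 28.2 for neutrophil-like, −18.2 for B cell-like and −1.88 for cDC-like cells, and in neutrophil-like cells S phase genes were at −0.20 and primary granule genes at 0.12. With the empty droplet test the B cell-like share was −18.4, the cDC-like share −1.58 and the neutrophil MHC class II median −1.62. At 20% mitochondrial UMIs the shares were 28.2 for neutrophil-like, −6.75 for monocyte-like and −1.51 for cDC-like cells, with Ptprj at 0.0108 and Itgam at −0.25 in B cell-like cells. At 5% they were 32.3 for neutrophil-like, −14.0 for B cell-like, −3.59 for NK/ILC-like and −2.67 for cDC-like cells. Also at 5% monocyte medians were 0.23 for oxidative phosphorylation and 0.60 for interferon, and in B cell-like cells Rgs1 was at −0.0873 and Itgam at −0.33. With doublets kept the neutrophil-like share was 28.3 and the cDC-like share −1.78. Neutrophil medians then were −0.12 for S phase, −0.32 for MHC class II and 0.28 for primary granules, the B cell inflammatory median 0.0792 and the NK/ILC MHC class II median −0.50, with Rgs1 at −0.0465 and Itgam at −0.29 in B cell-like cells. The cDC-like share was −1.56 at resolution 0.5 and −1.66 at resolution 2. With centred log values the B cell-like share was −4.98 and the cDC-like share −6.30, and cDC medians were −0.13 for oxidative phosphorylation, 0.18 for Tet genes and −0.20 for interferon. Rgs1 and Itgam in B cell-like cells were then at −0.22 and −0.12. In cDC-like cells Zbtb20 was at 0.0424, Ifi27l2a at −0.84, Ifi203 at −1.03, Fosb at 0.0126, Dnmt3a at 0.62 and Kdm6b at 0.17. Thinned to 500 UMIs, the cDC-like share was −2.33 and the medians were 0.0296 for B12 genes in NK/ILC-like cells and −0.79 for MHC class II in neutrophil-like cells. Oxidative phosphorylation was then at 0.12 in monocyte-like and 0.13 in NK/ILC-like cells, with Tet genes at 0.00795 and interferon genes at 0.28 in monocyte-like cells. Pcna was at 0.0237 in neutrophil-like, Tet2 at 0.0233 in monocyte-like and Itgam at 0.0903 in NK/ILC-like cells, and Zbtb20, Isg15 and Itgam were at 0.12, −0.44 and 0.21 in cDC-like cells. With unnamed clusters forced to a name the cDC-like share was −2.12. Among cells that are not neutrophil-like the differences were 0.433 for monocyte-like, 6.79 for NK/ILC-like, 2.72 for cDC-like and 0.0893 for T cell-like cells. Scaled by the median ratio of genes, oxidative phosphorylation was at 0.26 in monocyte-like and 0.30 in NK/ILC-like cells, interferon at 0.60 in monocyte-like and 0.45 in neutrophil-like cells, and Itgam at 0.0177 in neutrophil-like cells. Without the 20 most abundant genes oxidative phosphorylation was at 0.20 in monocyte-like and 0.22 in NK/ILC-like cells. As the mean of each cell's CPM, S phase was at −0.20 and MHC class II at −0.57 in neutrophil-like cells, immediate early genes at 0.0123 in NK/ILC-like cells, and oxidative phosphorylation at 0.10 in monocyte-like and 0.13 in NK/ILC-like cells. With genes of at least 200 UMIs S phase was at −0.34 in neutrophil-like cells. With clusters weighted alike monocyte values were 0.10 for oxidative phosphorylation, 0.42 for interferon, 0.00551 for Bcl2 and 0.0493 for Tet2, and the neutrophil interferon median was 0.25. The interferon median thus lay between 0.28 and 0.60 in monocyte-like and between 0.25 and 0.45 in neutrophil-like cells, and the neutrophil-like share between 28.2 and 32.3. No value was reached for the macrophage-like share where the class got no cluster (20% mitochondrial UMIs, doublets kept, resolution 0.5, centring). The same held for lists left with too few genes, namely after thinning B12 genes in B cell-like and cDC-like, S phase and primary granules in neutrophil-like, primary granules in monocyte-like, MHC class II in NK/ILC-like and Tet genes in cDC-like cells, and MHC class II in NK/ILC-like cells with genes of at least 200 UMIs. Cluster 5 genes were not computed anew where cells were clustered again.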

Other observations

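Cluster 5, which held B cell markers together with plasma cell genes such as Igha and is unnamed, made up 5.13% (308 cells) of the low-B12 and 4.59% (294 cells) of the high-B12 library. S100a4, S100a6 and Vim were among genes higher there in the high-B12 library. S100a4, a calcium-binding protein gene (ENSMUSG00000001020, chromosome 3, 90603771 to 90606045), was at 50.2 and 405 CPM, a ratio of 8.04 (6.64 to 9.87), and S100a6 at 744 and 3057 CPM, a ratio of 4.11 (3.90 to 4.33). Crip1 was at 1209 and 2808 CPM, Tagln2 at 160 and 306 CPM, Emp3 at 226 and 413 CPM, the vimentin gene Vim at 541 and 950 CPM and the cystatin C gene Cst3 at 250 and 424 CPM.

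Irf8, Cd72 and Cd22, genes active in B cells, were lower in cluster 5 of the high-B12 library. The transcription factor gene Irf8 was at 268 and 113 CPM, 2.36-fold lower (2.04 to 2.75), Egr1 at 242 and 121 CPM, and the inhibitory receptor genes Cd72 and Cd22 at 256 and 138 CPM and at 339 and 204 CPM. The Fc receptor gene Fcmr, a marker used to score this cluster, was at 414 and 239 CPM, Arhgap24 at 489 and 268 CPM, Ccnd3 at 264 and 150 CPM, Zbtb20 at 1004 and 630 CPM and Dusp2 at 328 and 206 CPM. These values belong to a cluster without a class and no explanation for them was tested.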
